A study of Mus musculus with 2 samples.

How the data were processed

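Total RNA of CD4 T cells from the spleens of Taf7 heterozygous and Taf7 knockout mice was hybridised to Affymetrix arrays, with 1 array per genotype. The deposited values are log2 gene-level signals made by the authors with the RMA algorithm in Affymetrix Expression Console version 1.1, per the submitters' processing notes and the series design text, which also states that they kept the core gene set. The design text names an exon array, whereas the probe table used here matches identifiers of the mouse gene-level whole transcript array; which of these was hybridised was not settled. The position of each probe in its gene and the genome build are not given in the sources used here.

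The table held 35556 rows, of which 21789 were transcript clusters with 1 gene symbol, 1621 had several symbols and 12146 none in the probe table. What the rows with no symbol measure is not given there. Only clusters with 1 symbol were named. The gene identifiers of 21698 of them were in the reference gene table of assembly GRCm38.p6, which was used for names and gene order only, and no symbol needed updating. For a gene with several clusters, as 999 of the 19938 genes had, the cluster of highest mean was taken. Genes with a mean over both arrays at or above the 50th percentile of all rows, a log2 value of 7.71, entered the counts, which left 10457 genes.

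The deposited values were compared with no further normalization, as the log2 difference of knockout minus heterozygote. With 1 array per genotype there is no estimate of error, so genes were counted at fixed sizes of 2-fold and 1.5-fold. Named are Taf7, the 15 genes with the largest and the 15 with the smallest difference above the filter, every TFIID subunit and sex-linked gene, and up to 3 members at each end of every gene list. Any other gene named is said to be chosen after its values were seen. The 30 gene lists, the counts and 9 alternative settings were fixed before the data were examined. For each list with at least 5 measured members, the percentile of its median difference was taken among 10000 random lists of the same size, matched in 20 bins of mean expression. This percentile describes these arrays and is not a test of the genotype.

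The list procedure was tested on simulated data. Of 100 random lists of 10 genes without a shift, 8% fell outside the central 95% range, and 78% did with a shift of 0.2 on the log2 scale. For lists of 30 genes these shares were 6% and 98%. Of 200 planted genes 193 were recovered, and for the other 7 another cluster was chosen.

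The alternatives were centring on the median difference, removal of a loess trend on the mean (span 0.3), quantile normalization, no filter, filters at the 25th and the 75th percentile, averaging of clusters, random lists not matched on expression, and list means in place of medians. Random lists not matched on expression were drawn from all 19938 genes, whose median difference was 0.06, against -0.05 above the filter. A list of well-expressed genes therefore tends to fall lower among them. An alternative with genes of 1 cluster only and 3 further gene lists, of regulatory T cell markers, memory markers and P-TEFb response genes, were chosen after the data had been seen. Gene length was not tested because no build is named. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.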

Results

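Gene expression was measured in naive-enriched CD4 T cells from mouse spleen, from 1 Taf7 knockout sample and 1 Taf7 heterozygous sample, with 1 array per genotype. The cells were sorted for high T cell receptor beta and CD4 and enriched for low surface CD44, a protein that is abundant on activated and memory T cells. Per the labels, in the knockout the floxed Taf7 allele had been removed by a Cre transgene named 8EIII-cre, and the heterozygote carried the same floxed and null alleles without Cre. Both mice were on a mixed C57/BL6 and 129 background. The deposited log2 values had a median of 7.68 on the heterozygous array and 7.75 on the knockout array, and both arrays reached 14.56. Across the 10457 genes above the filter on low values the arrays correlated with a Pearson r of 0.982 and a Spearman rho of 0.981, computed across genes, which are not independent replicates. No difference given here has a replicate check, so no test between the genotypes was run, and the number of arrays limits the precision of every value.

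The first question was how the deleted gene and its complex appeared on the arrays. Taf7, a subunit of the general transcription factor TFIID, had a log2 value of 8.34 in the heterozygote and 7.79 in the knockout, a difference of -0.55 or 1.46-fold lower. That difference lay at percentile 3.76 among genes of similar mean expression, and the knockout value was close to the filter value of 7.71. Of the 18 TFIID subunits measured, including Taf7, 10 were higher and 8 lower, and none differed by 1.5-fold among the 17 above the filter. Taf5, a scaffold subunit, was the highest with a log2 difference of 0.55 (1.47-fold higher), followed by Taf12 at 0.35 and Taf8 at 0.30. After Taf7 the lowest were Taf2 at -0.35, Taf9 at -0.34 and Taf9b at -0.31. The clusters of Taf10 disagreed in sign, at 0.11 and -0.14. Tbp, the TATA-binding subunit, was at -0.00, and Taf7l, a Taf7 paralog below the filter, was at 0.22. The median of the TFIID subunits was 0.07, at percentile 98.97 of matched random lists, but at 88.9 when the clusters of a gene were averaged. With random lists not matched on expression it was at percentile 57.3, which also carries the offset of the arrays with signal. Where the Taf7 probes lie relative to the deleted part is not given in the sources used here, and a probe outside that part would not check the genotype.

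Lists of the rest of the transcription machinery lay inside the range of random lists matched on expression, with single members apart. Hexim1, an inhibitor of the elongation kinase P-TEFb, was 2.05-fold higher in the knockout, from a log2 value of 9.40 to 10.44. Polr2a, the largest subunit of RNA polymerase II, was higher by 0.58 on the log2 scale, and Med24 of the Mediator complex was at -0.55. Among the other general transcription factors, Gtf2a1 was at 0.31, Gtf2b at 0.30 and Mnat1, a subunit of the TFIIH-associated kinase, at -0.43. The list medians were -0.01 for general transcription factors and P-TEFb (percentile 91.3), -0.05 for RNA polymerase II subunits (54.7), -0.08 for Mediator subunits (46.5) and -0.02 for the core spliceosome (86.2). The mean of the polymerase list was 0.01, of the opposite sign to its median. With random lists not matched on expression, Mediator subunits, of which 22 of 32 were lower, lay at percentile 0.39. That position is no evidence about Mediator, because such random lists include weakly expressed genes, whose differences were higher.

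The second comparison asked which transcripts differed between the knockout and the heterozygous T cells. Few genes differed by 2-fold, and most of those were lower in the knockout: 4 genes were higher and 34 lower among 10457. At 1.5-fold, 47 genes were higher and 332 lower, so that 96.4% of genes differed by less. The 4 genes at least 2-fold higher were Neto2 (2.34-fold), an auxiliary subunit of kainate receptors, Caprin2 (2.24-fold), the histone H2B gene H2bc4 (2.20-fold) and Hexim1. Neto2 was at 7.51 in the heterozygote, below the filter value of 7.71, so its fold rests on a low value. The next highest were Baiap2 and Ms4a6c, both with a log2 difference of 0.99, and Phlda3, a p53 target, at 0.90. Chrnb2, Cfap74, Mir505, Ndrg1, Pik3r3, Zfp619, Mllt11 and Ms4a6d lay between 0.76 and 0.83.

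Among genes lower in the knockout, Igha, the constant region of immunoglobulin A heavy chain, was 4.03-fold lower, the largest difference with the cluster of highest mean. Its other transcript cluster was at -0.90 on the log2 scale, and with its clusters averaged the difference of Igha was -1.46, smaller in size than those of Cpm, Nrp1, Igsf23 and Ctla4 and about that of Tent5a averaged likewise. Cpm, a membrane carboxypeptidase, was 3.39-fold lower, Nrp1, a coreceptor found on regulatory T cells, 3.19-fold lower, and Igsf23 was at -1.58 on the log2 scale. The knockout values of Igha, 7.13, and Nrp1, 7.08, were below the filter value of 7.71, so both folds rest on low values. Ctla4, an inhibitory receptor, was 2.82-fold lower, Cd55, a complement regulator, 2.74-fold lower, and Slc28a2b 2.74-fold lower. Cd44 was 2.55-fold lower, but CD44 was also a sorting marker, so its value is not separate from how the cells were obtained. Slc16a5, Lypd6b, Aldh2, Tent5a, Ust, Adh1 and Tlr7 had log2 differences from -1.34 to -1.23, and the other cluster of Tent5a was at -1.66. The median difference over all genes was -0.05, with a central 95% range of -0.62 to 0.39. Rows below the filter had a median of 0.12, so the offset between the arrays varied with signal. Of the genes at 1.5-fold, 87.6% were lower, and 77.6% were lower after the median difference was subtracted.

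**Figure D1:**
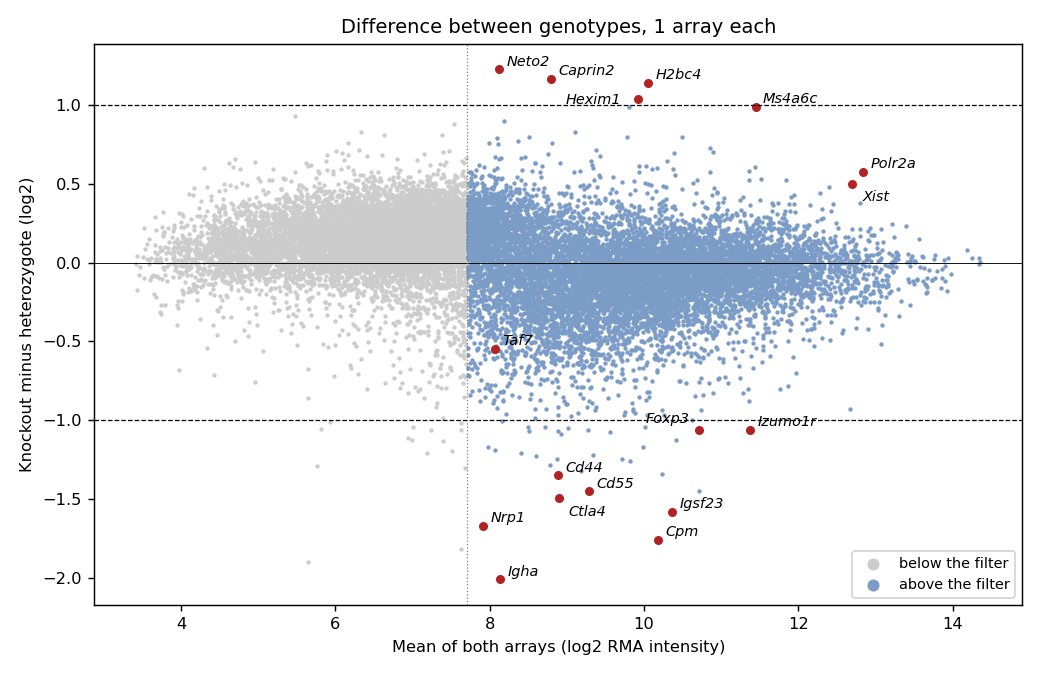
Log2 difference (knockout minus heterozygote, y axis) against the mean log2 value of both arrays (x axis), with 1 point per gene, in blue above the filter and in grey below it. Most blue points lie within the central 95% range of -0.62 to 0.39, and 34 of them lie at or below a 2-fold lower value against 4 at or above a 2-fold higher value.

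T cell activation and regulatory genes were lower in the knockout. Of 31 activation and memory genes measured, 21 were lower and 10 higher, and of the 23 above the filter 5 were lower by at least 1.5-fold and none higher. Their median difference was -0.26, below that of every one of 10000 matched random lists. Ctla4 and Cd44 were the lowest, then Izumo1r, the folate receptor 4 gene, at 2.09-fold lower, while Cd69, an early activation marker, was at 0.44 and Tox2 at 0.23. Among 22 helper and regulatory lineage genes, 14 were lower and 8 higher, with a median of -0.09 at percentile 0.05. Only 9 of the 22 were above the filter, 3 of them lower by at least 1.5-fold and none higher. Of the 8 higher, only Tbx21 was above the filter, and rows below it had a median difference of 0.12. Nrp1, Foxp3, the transcription factor that defines regulatory T cells, and Ikzf2, which encodes Helios, were lower, Foxp3 by 2.09-fold from a log2 value of 11.25 to 10.19 and Ikzf2 by 1.96-fold. Gpr83 at -0.02 and Ikzf4 at -0.20, both also linked to regulatory T cells, differed less, and Tbx21, the T helper 1 factor T-bet, was at 0.58. Tbx21 passed the filter by its mean, with a value of 7.45 in the heterozygote, below the filter value of 7.71.

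The 25 T cell receptor complex and proximal signalling genes had a median of -0.00 at percentile 81.6, and 24 of them were within 1.5-fold. The exception was Trat1, a receptor-associated adaptor, at -0.73, followed by Cd3d at -0.50 and the costimulatory receptor Cd28 at -0.42. The 22 naive and quiescent genes had a median of -0.05 at percentile 42.2, with Cd55 as the lowest, Dapl1 at -0.52, Cd27 at -0.35, and Tob1, an antiproliferative factor, at 0.43. Their mean was -0.13, at percentile 2.34 among the means of random lists. Cytotoxic lymphocyte genes, with 8 of 19 above the filter, had a median of 0.01 at percentile 8.15. Their mean was of the opposite sign, -0.16, at percentile 0.04. Klrd1, encoding CD94, was 2.13-fold lower, Eomes 1.81-fold lower and Cst7 1.68-fold lower. Thymocyte and recent emigrant genes, with 6 of 14 above the filter, had a median of 0.06 at percentile 40.8 and a mean of -0.07. Ccr9, a gut-homing chemokine receptor, was at -0.76.

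**Figure D2:**
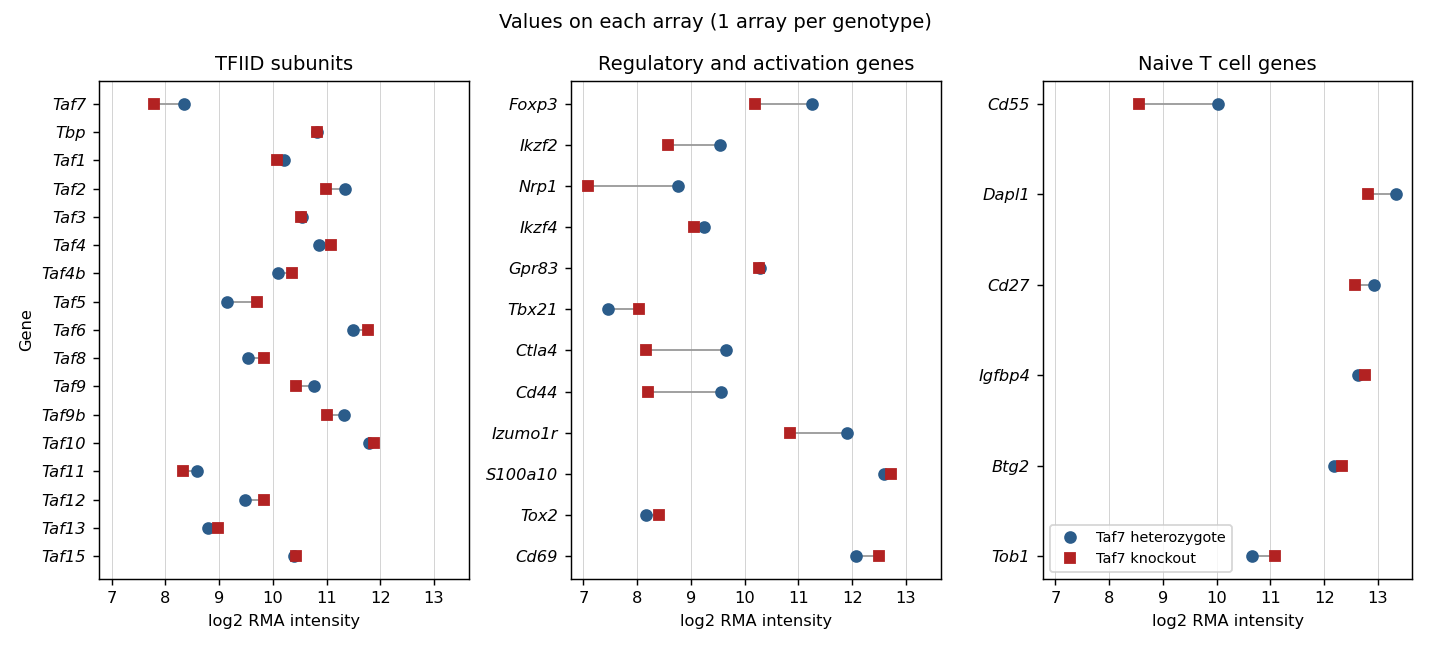
Log2 expression of named genes, each point being the value on 1 array, as blue circles for the heterozygote and red squares for the knockout, with no error bars because each genotype has 1 array. Foxp3, Ctla4 and Nrp1 lie lower in the knockout, and Cd69 and Tbx21 lie higher.

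Markers of other cells that a spleen sort could hold had medians inside the range of random lists, except for those of natural killer cells. B cell markers had a median of 0.15 (percentile 73.0), myeloid markers 0.14 (43.3), erythroid markers 0.17 (68.5), platelet markers 0.22 (93.6), CD8 T cell markers -0.08 (11.5) and plasma cell markers 0.02 (8.74). Most of these markers were below the filter: 14 of 19 B cell, 27 of 30 myeloid and 9 of 9 natural killer cell markers were. Natural killer cell markers had a median of -0.00 at percentile 2.15, and their mean was 0.05 at percentile 13.2. Cd72, a B cell coreceptor gene, was at -0.80, and Itgb3, an integrin of platelets, at -0.61. The plasma cell list had a mean of -0.24 at percentile 0.08, which rested on Igha: the 6 plasma cell genes with 1 cluster, without Igha, had a mean of 0.05. Xist, the RNA of the inactive X chromosome, was at 12.5 in the heterozygote and 12.9 in the knockout, while the Y-linked genes lay between 4.37 and 5.76 on both arrays. Of 4 genes listed for C57/BL6 and 129 strain variants, 3 were lower and 1, Nnt at 0.19, higher, with a median of -0.24. Among 31 genes near Taf7 on its chromosome, the median was 0.04 at percentile 53.7, and Slc25a2, which lies next to Taf7 in the reference order, was 1.61-fold higher.

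Cytosolic ribosomal protein genes were lower as a group. Of 56 measured, 51 were lower and 5 higher, and the median of -0.21 was below that of every matched random list. Rps3a1 was at -0.77, the only member lower by 1.5-fold, and Rps19 at 0.14. Ribosomal proteins have many near-identical pseudogenes, which makes single members uncertain; the listed genes with 1 cluster had a median of -0.22 at percentile 0.06. Oxidative phosphorylation genes had a median of -0.06 at percentile 42.3 with 53 of 71 lower. With random lists not matched on expression they lay at percentile 0.02, which carries the offset of the arrays with signal. Glycolysis enzymes had a median of -0.06 at percentile 30.2.

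Immediate early and stress genes were higher relative to genes of the same expression. Of 35 measured, 23 were higher and 12 lower, with a median of 0.06 at percentile 99.5. With random lists not matched on expression the median was at percentile 52.7, which also carries the offset of the arrays with signal. Cd69, Dusp2 at 0.39 and Dusp1 at 0.35 were the highest, and Rgs1, a regulator of G protein signalling, was the lowest at -0.96. Interferon-stimulated genes had a median of -0.09 at percentile 18.9, with 25 of 33 lower, and a mean of -0.22 at percentile 0.01. With random lists not matched on expression the median was at percentile 0.16, which again carries the offset with signal. Ifit3 was 1.83-fold lower, Ifit2 1.77-fold lower and Oasl2 1.67-fold lower, while Oas2 was at 0.29 and Irf7 at 0.23. Genes of class I antigen presentation had a median of -0.03 at percentile 59.8, with the immunoproteasome subunit Psmb9 at -0.60. Replication-dependent histones had a median of 0.12 at percentile 95.5 and a mean of 0.16 at percentile 99.9, with H2bc4 and the linker histone H1f2 at 0.60 the highest. Cell cycle genes had a median of 0.09 at percentile 48.2, with Ccnb2 at 0.31 and Ccne1 at -0.45. Apoptosis regulators and p53 targets had a median of 0.00 at percentile 72.0, with Phlda3 the highest, Pmaip1 at 0.39 and the death receptor Tnfrsf10b at -0.50. In all, 6 of the 28 lists with a percentile lay outside the central 95% of random lists, where the nominal rate gives 1.4. Simulated lists without a shift fell outside at a rate of 8% (10 genes) and 6% (30 genes). Both rates take the genes of a list as independent. Genes of a list can vary together and lists share genes, such as Cd69, so neither rate is that expected without a genotype effect.

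**Figure D3:**
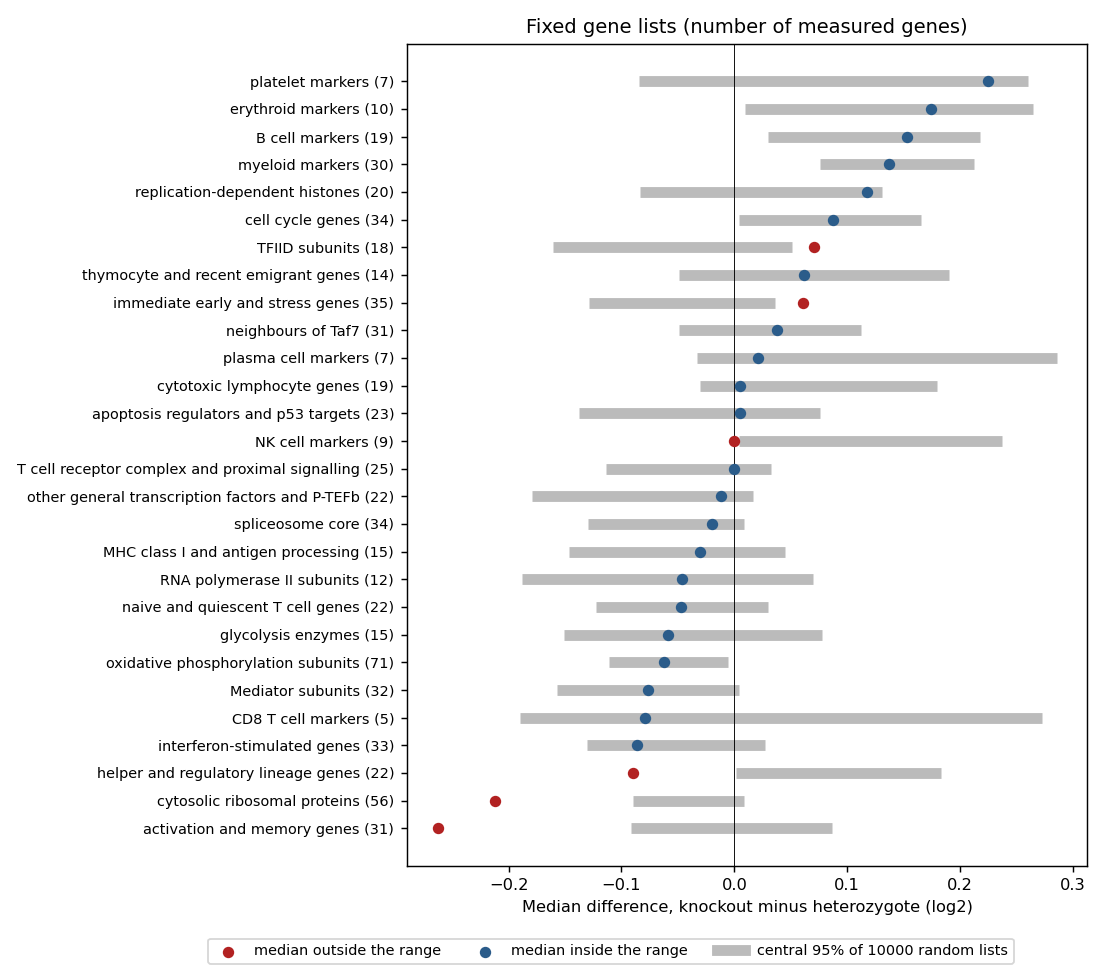
Median log2 difference (knockout minus heterozygote, x axis) of each fixed gene list with a percentile, drawn as a point on the central 95% range of 10000 random lists matched on mean expression. Activation and memory genes at -0.26 and cytosolic ribosomal proteins at -0.21 lie below their ranges.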

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

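Among rows that no comparison used, 11 of those with no gene symbol were at least 2-fold higher in the knockout and 45 at least 2-fold lower, of 5412 above the filter. Their log2 differences reached 2.05 and -2.85, larger in size than those of the named genes. The probe table does not say what these rows measure, so some may be control probes and not transcripts. These data lie outside the comparisons, and the differences came to 1.03% of such rows, against 0.363% of the genes with 1 symbol. With 1 array per genotype it was not tested whether these rows are noisier. Of 831 clusters with several symbols above the filter, 1 was at least 2-fold lower, with a log2 difference of -1.05.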

How the results depend on the processing

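The setting with genes of 1 cluster only was chosen after the data had been seen. Each genotype has 1 array, so no array could be left out. No paired analysis was possible because each genotype has 1 array and no shared animal is named. The count of genes at least 1.5-fold higher was 71 after centring and 91 with no filter, against 47, because centring adds a constant to every difference and no filter admits more genes. With the filter at the 75th percentile, which admits fewer genes, 2 genes were at least 2-fold higher and 12 lower, 16 at least 1.5-fold higher and 105 lower, and 12 of the 30 named genes with the largest and smallest differences were shared. The natural killer cell list reversed sign, from -0.00 to 0.048 after centring and 0.050 as a mean; its median lies next to 0. Other lists whose main medians lay inside the random range also changed sign, 6 with centring, which adds 1 constant to every gene and says nothing of a list. There were 10 with the loess trend removed, 8 with quantile normalization and 4 as means. Of these 4, the cytotoxic and plasma cell lists lay outside the range as means, at percentiles 0.04 and 0.08. Of the other values of gene lists under alternatives, 237 stayed within 1 SD of the random medians and 61 moved further. Of the 61, 14 came from centring, which shifted the random lists alike and left every percentile unchanged, so they say nothing of a list. Another 19 came from removal of the loess trend and 15 from quantile normalization, which also shift the random lists. The 237 include 30 values each from no filter, from either other filter and from random lists not matched on expression. List medians use all measured members, so these values were identical to the main ones and could not have moved. Of the values of single named genes, 728 stayed within the robust SD of genes of similar mean and 4 did not, those of Igha, Tent5a, Polr2c and Top2a with clusters averaged. The 728 include 183 values after centring, which could not have moved. Centring subtracts the median difference, -0.048, which is smaller in size than each of these SDs. Averaging likewise left genes of 1 cluster unchanged. The Taf7 level differed by between -0.63 and -0.50. The number of lists outside the central range was between 5 and 9.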

Other observations

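The tests of regulatory and memory markers, of P-TEFb response genes and of the share of T cell list genes were chosen after overlapping results had been seen; removal of the loess trend was a planned setting, and its use against these patterns was chosen afterwards.

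Genes named here were chosen after their values were seen, and no theme among them was tested. Cd40lg, the CD40 ligand through which T cells help B cells, had a log2 value of 11.13 in the heterozygote and 10.13 in the knockout. The costimulatory receptor Cd226 was 2.06-fold lower, the receptor Gpr174 2.25-fold lower and the cannabinoid receptor Cnr2 2.28-fold lower. The knockout value of Cnr2, 7.48, was below the filter value of 7.71. Asah1, the acid ceramidase, was 2.09-fold lower, the GTPase regulator Arhgap20 2.31-fold lower and Fam111a 2.33-fold lower. With smaller differences, Il2ra, the alpha chain of the interleukin-2 receptor, was at -0.83 and Icos at -0.66.

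Regulatory and memory T cell genes were lower in the knockout sample. After removal of a loess trend between the arrays the activation and memory list had a median of -0.27 and the helper and regulatory list -0.16. A trend with mean expression therefore does not account for the lower medians. The percentiles after removal, below all random lists and 0.03, are no separate evidence. They could hardly move, because the random lists were already matched on mean expression. A candidate explanation is a smaller share of regulatory T cells: 11 further markers outside the fixed lists had a median of -0.35 at percentile 0.02, and with 9 that also stand in fixed lists the 20 had a median of -0.30, below all random lists. Memory cells, which the low CD44 enrichment would remove, may also be fewer, on weaker grounds. Among 5 further markers outside the fixed lists, 4 were lower and 1 higher, with 1 lower by at least 1.5-fold. Their median was -0.28 at percentile 1.82, close to the range edge of -0.26. Their median heterozygote value was high, 12.0, so they may not be particular to memory cells. The full list of 22 had 13 lower and 9 higher, with a median of -0.25 below all random lists. It holds 17 genes of fixed lists and mostly restates the pattern. Lrrc32 at -0.96 and Ecm1 at 0.24, chosen after their values were seen, did not go together, and an effect of the genotype within each cell stays open and untested. For every pattern here, loss of Taf7 cannot be told apart from the Cre transgene, which only the knockout carried. Nor can it be told apart from differences between the animals on their mixed background, with 1 array per genotype.

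Hexim1 and H2bc4 were among the 4 genes 2-fold higher. The loess trend does not account for them, since at their mean expression the trend itself was -0.075, which would lower them. A response to release of P-TEFb might raise such genes, but 6 response genes, 2 of them also in fixed lists, had a median of 0.05 at percentile 38.84. The bound written against this explanation was percentile 50, which the value met; the bound was wrong because 0.05 lies well inside the central range of the random medians, -0.15 to 0.25, and members went both ways, with H1f2 at 0.60 and H2bc21, chosen after its value was seen, at -0.36. The test was first read as excluding the explanation and was reread as leaving it open after its value was seen.

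More genes were 2-fold lower than higher. After removal of the loess trend 84.6% of the genes at 2-fold were lower, so the trend does not account for the asymmetry. Loss of regulatory and memory cells alone could lower many genes. Of those lower, 14.7%, 5 of 34, were in the activation, lineage and further regulatory and memory lists, and 7 of 34 in any of the fixed T cell lists. The 14.7% is under the written bound of 25%, and this test too was first read as excluding the explanation. It was reread as leaving it open because the lists hold only part of the genes of such cells. The activation, lineage and further regulatory and memory lists hold 23, 9, 15 and 15 genes above the filter, with overlaps, of 10457. The 5 are more than the share of these lists among all genes, but 3 stand in the activation list and 2 in the lineage list. The pattern was seen in those 2 lists, and Cd44 was a sorting marker, so the excess restates the pattern. The further regulatory and memory lists each had 0 genes lower by 2-fold. The share of list genes therefore does not decide the question.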
